A study of Mus musculus with 16 samples.

How the data were processed

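RNA of mouse pre-B cells was extracted with PeqGOLD TriFast, selected for poly(A) and made into libraries with a TruSeq or a NEBNext kit, and the libraries were sequenced on an Illumina HiSeq instrument. Which library had which kit is not stated. The submitters' notes name CASAVA 1.8.2 and the genome build mm10, and the aligner and the counting program are not given in the sources used here. The strand on which reads were counted is not stated either. Per the file headers, the deposited tables hold counts of reads per gene and lane, not normalized, as total and unique exon reads and as total and unique gene reads. They also hold RPKM columns and a fold change made by the authors, which its header says is of original values. The RPKM columns were not used, the fold change was used only as an alternative, and no p-value of the authors was used. The 3 tables list the same 38918 features, 0 columns were left unmatched to a sample, and the control counts are the same in each table.

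The 16 samples carry 1 index sequence per condition and lane names, so they were read as 4 lanes of each of 4 libraries. Lanes were summed, and no pair of lanes held identical counts. Lanes held between 7631791 and 8709054 total exon reads. Between lanes of a library, the chi-square per degree of freedom was 1.24 to 1.32 for total exon reads and 0.992 to 1.01 for unique exon reads, over genes with at least 20 reads, and the lowest correlation of log values was 0.995. Genes with at least 1 CPM numbered 10871 in the control library, 10915 at 0.5 h, 10820 at 1.5 h and 10820 at 5 h. Unique reads made up 84.0, 84.4, 84.5 and 84.6% of exon reads in the same order. A count of 0 allows up to 3 counts, which is 0.0869, 0.0886, 0.0919 and 0.0976 CPM. Reads without molecular identifiers are not independent molecules, so these limits and all intervals of ratios cover counting error only.

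Total exon reads were scaled to CPM. For each gene the log2 ratio was taken after adding 1 CPM to both libraries. A gene was called higher or lower with a ratio of at least 2-fold on this scale and at least 5 CPM in the higher library. Printed folds are ratios of CPM with nothing added, with exact Clopper-Pearson 95% intervals from the binomial split of the reads of both libraries. The comparisons were 0.5, 1.5 and 5 h against control and 5 h against 1.5 h. There is 1 library per condition, so no test across conditions was run. The overlap of comparisons that share the control was set beside 100 simulations of unchanged genes with Poisson counts and beside a split of the control lanes.

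The rule for named genes took, in each comparison, the 10 genes with the largest ratios in each direction among those called, with predicted genes left out. It also took the parts of the construct and the receptor components in every library, and up to 4 measured members of each gene list with the largest ratios. It added Rag1, Rag2, Irf4, Ikzf3, Foxo1, Myc, Ccnd2, Ccnd3, Il7r and Bcl6. Not every gene that this rule names is reported here. Gene lists were written from general knowledge of the cells. They covered transgene parts, receptor components, immediate early genes, targets of NF-kB and NFAT, of FoxO, of IL-7 and STAT5, of MYC in ribosome biogenesis and of p53, B lineage transcription factors, light chain recombination, pro-B markers, B cell maturation, plasma cells, the G1, S and G2/M phases, the unfolded protein response, heat shock, sterol synthesis, the interferon response, housekeeping, and markers of T and NK, myeloid, erythroid and megakaryocyte, and stromal cells. These 25 lists hold 474 genes, of which 465 were found in the tables by symbol. Each list is described by the median log2 ratio of members with at least 1 CPM in either library, with an order-statistic 95% interval over members. Its percentile among 10000 random lists, matched on mean expression in 20 bins, is a description and not a test. The sample groups, comparisons, rule of size, rule for named genes, 25 lists and most alternatives were fixed before the data were examined.

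Alternatives were TMM factors and DESeq2 size factors, pseudocounts of 0.1 and 5 CPM, floors of 1 and 20 CPM and none, ratios of 1.5-fold and 4-fold, a counting interval that excludes 1, leaving out each lane, lanes as blocks, list means, lists centred on the median of all genes, and lists measured from 5 CPM. Unique exon reads, total gene reads and the authors' fold change were added as alternatives after the data were seen. Counts with known changes were also simulated by Poisson draws from the rates of 1 library. In each comparison 50 of 50 genes were called at 3-fold, 8-fold and 0.333-fold, 0 of 50 at 1.5-fold, and 0 of at least 9173 unchanged genes. These draws hold counting error alone, with no difference between libraries, so the 0 is not a rate of false calls for the real libraries. GC content was taken from GENCODE vM21 transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 gave the scaling factors.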

Results

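RNA was sequenced from mouse pre-B cells that lack the adaptor protein BLNK and that carry a retroviral BLNK-ERt2 fusion. Pre-B cells are precursors of B lymphocytes, and their receptor, the preBCR, pairs an immunoglobulin heavy chain with a surrogate light chain. BLNK couples this receptor to its downstream enzymes. The ERt2 part is an oestrogen receptor domain that makes the fused protein depend on tamoxifen. The 4 conditions were a control and cells stimulated for 0.5, 1.5 and 5 h, and the stated purpose was to find genes that respond to preBCR signalling. Whether the control cells received the vehicle of the inducing drug, and for how long, is not stated. The 16 samples are 4 sequencing lanes of each condition that share 1 index, and they were summed to 1 library per condition. Lanes of a library differed by no more than sampling noise in uniquely placed reads, with a chi-square per degree of freedom from 0.992 to 1.01. In total exon reads, on which calls and intervals rest, it was 1.24 to 1.32, more than sampling noise. Total exon reads were 34533362 in the control library, 33864004 at 0.5 h, 32631061 at 1.5 h and 30746189 at 5 h. With 1 library per condition there is no replicate spread, so no p-value is given and the 95% intervals of fold values cover counting error only. Given the excess between lanes in total exon reads, these intervals can be too narrow for genes with few uniquely placed reads.

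Blnk (chromosome 19, 40928927 to 40994535, mm10) stood at 3516 CPM (reads of the gene per 1000000 total exon reads) in the control library, from 121425 reads. Its level was 1.08-fold higher at 0.5 h (1.07 to 1.09), 1.02-fold higher at 1.5 h (1.02 to 1.03) and 1.0-fold at 5 h (1.0 to 1.01). Esr1 (chromosome 10, 4611593 to 5005614), the gene of the oestrogen receptor, stood at 94.7 CPM in the control library and was 1.14-fold higher at 0.5 h (1.09 to 1.19), 1.15-fold at 1.5 h (1.09 to 1.20) and 1.12-fold at 5 h (1.07 to 1.18). The counts do not separate the construct from the endogenous loci. The list of these transgene parts had median log2 ratios of 0.15, 0.11 and 0.09 at the 3 times. Genes of the receptor itself were abundant: in the control library Ighm, the mu heavy chain, stood at 5997 CPM, Vpreb1 and Igll1, the surrogate light chain, at 1551 and 1540 CPM, and Cd79a, a signalling chain of the receptor, at 1783 CPM.

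Expression 0.5 h after stimulation was compared with control to find the first responders. Immediate early genes, which are induced without new protein synthesis, were higher as a group. Egr1 (chromosome 18, 34859823 to 34864984), a zinc finger transcription factor, went from 1.77 CPM in the control library to 153 CPM, 86.8-fold higher (67.4 to 114). Nr4a1 (chromosome 15, 101266846 to 101274792), an orphan nuclear receptor, was 7.40-fold higher (6.19 to 8.90), and Fosb and Jun, subunits of the AP-1 transcription factor, were 10.8-fold (7.63 to 15.8) and 5.09-fold higher (4.83 to 5.36). A gene counts as measured with at least 1 CPM in either library. Of the 32 measured genes of the immediate early list, 13 were called higher and 0 lower, with a median log2 ratio of 0.71 (0.45 to 1.56), above all 10000 random lists of matched expression. A call means at least 2-fold after adding 1 CPM to both libraries, with at least 5 CPM in the higher library.

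Targets of NF-kB and NFAT, transcription factors of antigen receptor signalling, were also higher at 0.5 h. Of 19 measured members 3 were called higher: the chemokine gene Ccl3 at 8.04-fold (5.67 to 11.7), Nfkbid, a nuclear regulator of NF-kB, at 3.29-fold (3.02 to 3.59), and the cytokine gene Tnf at 2.36-fold (2.05 to 2.73). The list median was 0.26, above all random lists. Myc (chromosome 15, 61985391 to 61990374), a transcription factor that drives growth, went from 293 to 923 CPM, 3.15-fold higher (3.08 to 3.22). Dusp2, a phosphatase that acts on MAP kinases, was 3.48-fold higher (3.26 to 3.71). In the list of IL-7 and STAT5 targets Myc and Cish, a suppressor of cytokine signalling, were called higher, and the median of the 21 measured members was 0.00. Cish was 2.41-fold higher (2.28 to 2.56), with 38% of its reads uniquely placed. In the unfolded protein response list 1 of 18 genes was called, Ppp1r15a, a regulator of translation, at 2.44-fold (2.24 to 2.67), and the median was 0.15. Transcription factors of the B lineage had a median of 0.08 with 0 of 25 called. Among them Pax5, which maintains B cell identity, was 1.44-fold higher (1.4 to 1.48).

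In all, 27 genes were called higher and 2 lower at 0.5 h among the 9516 genes with at least 5 CPM in either library. The lower genes included Ramp2, a receptor accessory protein, at 2.23-fold lower (1.95 to 2.56), but almost none of its reads were uniquely placed (0.05%). It had 0 unique reads in the control library and 1 at 0.5 h, too few for a direction. Its log2 ratio of -1.08 became -0.93 without lane 1 and -0.81 without lane 2, each of which ends the call. The other lower gene was the predicted gene Gm8399, which was chosen for naming after its values were seen. Its log2 ratio of -1.20 became -0.95 without lane 1, which ends the call, and it had 0 unique reads in both libraries. With a pseudocount of 5 CPM 19 higher calls and 0 lower ones were left. Among those that ended were the calls of Tnf (log2 ratio 0.88), Fos (0.9996), Ramp2 (-0.85) and Gm8399 (-0.93).

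**Figure D1:**
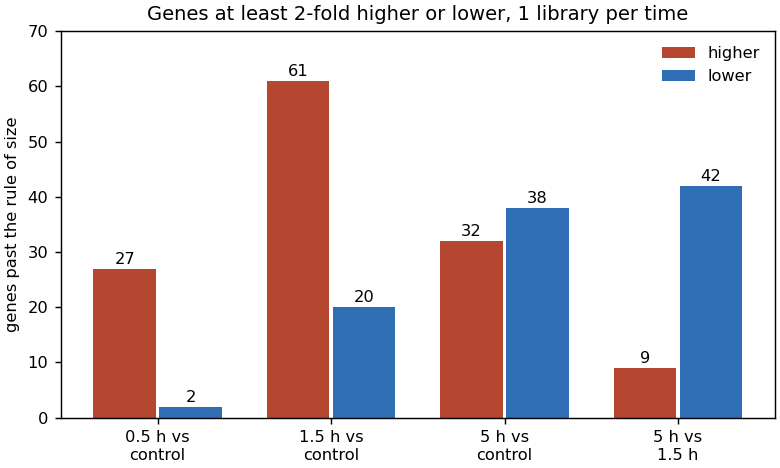
Bars show the number of genes called higher (red) or lower (blue) in each comparison, from 1 library per time. Higher calls outnumber lower ones at 0.5 h (27 and 2) and at 1.5 h (61 and 20), and lower calls outnumber higher ones at 5 h (38 and 32) and from 1.5 to 5 h (42 and 9). The order at 5 h reverses with a pseudocount of 5 CPM, with a floor of 20 CPM and in total gene reads.

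At 1.5 h, Irf4 and genes of ribosome biogenesis were among those higher than in control. Irf4 (chromosome 13, 30749226 to 30766927), a transcription factor needed for light chain gene rearrangement, went from 142 to 445 CPM, 3.12-fold higher (3.03 to 3.23). Hivep2 (chromosome 10, 13966379 to 14151376), a zinc finger DNA-binding protein, was 3.02-fold higher (2.91 to 3.13), and Myc was 2.99-fold higher (2.92 to 3.06). Egr1 was 6.96-fold higher (5.30 to 9.26) at 12.3 CPM. Of 31 measured immediate early genes 7 were called higher, with a median log2 ratio of 0.47, above all random lists. Nr1d1, a nuclear receptor of the circadian clock, was 3.41-fold higher (3.0 to 3.88). The list of B lineage transcription factors had a median of 0.026 with 0 of 24 called.

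Genes of the list of MYC targets in ribosome biogenesis were higher together at 1.5 h. All 30 measured members had ratios above 0, with a median of 0.51 (0.37 to 0.71), and 5 were called. With a pseudocount of 5 CPM the calls of Ppan and Rrs1 ended, each at a log2 ratio of 0.99. Examples are Polr1b, a subunit of RNA polymerase I, at 2.42-fold (2.25 to 2.61), and Gnl3, which encodes the nucleolar protein nucleostemin, at 2.28-fold (2.17 to 2.39). In the unfolded protein response list 0 of 18 genes were called, and the median was 0.25, with an interval that includes 0 (-0.029 to 0.33). In this list Atf4, a stress-responsive transcription factor, was 1.78-fold higher (1.73 to 1.83). NF-kB and NFAT targets had a median of 0.17 with 1 gene called, Ccl3 at 7.5-fold (5.27 to 10.9). The heat shock list had a median of 0.22 with 0 of 12 called. Sterol synthesis genes had a median of 0.15 with 0 of 22 called.

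Targets of FoxO transcription factors, which PI3 kinase signalling holds back, had the opposite direction at 1.5 h. Of 24 measured members 20 had ratios below 0, with a median of -0.48 (-0.80 to -0.20), below all random lists, and 1 was called. Ccng2, a cyclin linked to cell cycle arrest, was 1.89-fold lower (1.82 to 1.97), and Cdkn1b, the inhibitor of cyclin-dependent kinases p27, was 1.51-fold lower (1.45 to 1.56). Foxo1 itself (chromosome 3, 52268337 to 52350109) went from 170 to 100.2 CPM, 1.70-fold lower (1.63 to 1.77). The called member was Rag1, the recombinase, at 4.16-fold lower (3.07 to 5.74), but 8% of its reads were uniquely placed. Its unique reads numbered 17 in the control library and 3 at 1.5 h, 5.38-fold lower (1.56 to 28.7), a level under the floor of 5 CPM. With a pseudocount of 5 CPM its log2 ratio of -1.56 was -0.82, which ends the call.

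The light chain recombination list was mostly lower at 1.5 h, with 12 of 17 measured members below 0 and 5 above. Its median was -0.19 (-0.38 to -0.018). Irf4 and Dclre1c, which encodes the hairpin-opening nuclease Artemis and was 2.15-fold higher (2.0 to 2.30), were called higher, and Rag1 lower. Among the 21 IL-7 and STAT5 targets 10 were above 0, with a median of -0.14, and Myc was the 1 called, higher. The kinase gene Pim2 was 1.97-fold lower (1.85 to 2.10) and Bcl2l1, a survival gene, 1.8-fold lower (1.69 to 1.90), both outside the rule. Il7r, the IL-7 receptor, was 1.32-fold lower (1.25 to 1.39). Receptor components went both ways, with 6 of 20 above 0, 14 below and 0 called. Cbl, a ubiquitin ligase, was 1.36-fold higher (1.29 to 1.42), Syk, the kinase that acts on BLNK, 1.46-fold lower (1.42 to 1.50), and Pik3cd, a PI3 kinase subunit, 1.52-fold lower (1.50 to 1.55). Cyclin D2, Ccnd2, was 1.46-fold higher (1.39 to 1.53).

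Across all genes at 1.5 h, 61 were called higher and 20 lower of 9512. The lower set was headed by Pgf (chromosome 12, 85166639 to 85177296), a growth factor of the VEGF family, at 4.26-fold lower (3.36 to 5.47). B3gnt8, a glycosyltransferase, was 3.03-fold lower (2.63 to 3.5) and Arhgap25, a regulator of Rac, 2.59-fold lower (2.33 to 2.89). Of the 61 higher genes 52 passed the rule in unique reads alone, as did 14 of the 20 lower ones.

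**Figure D2:**
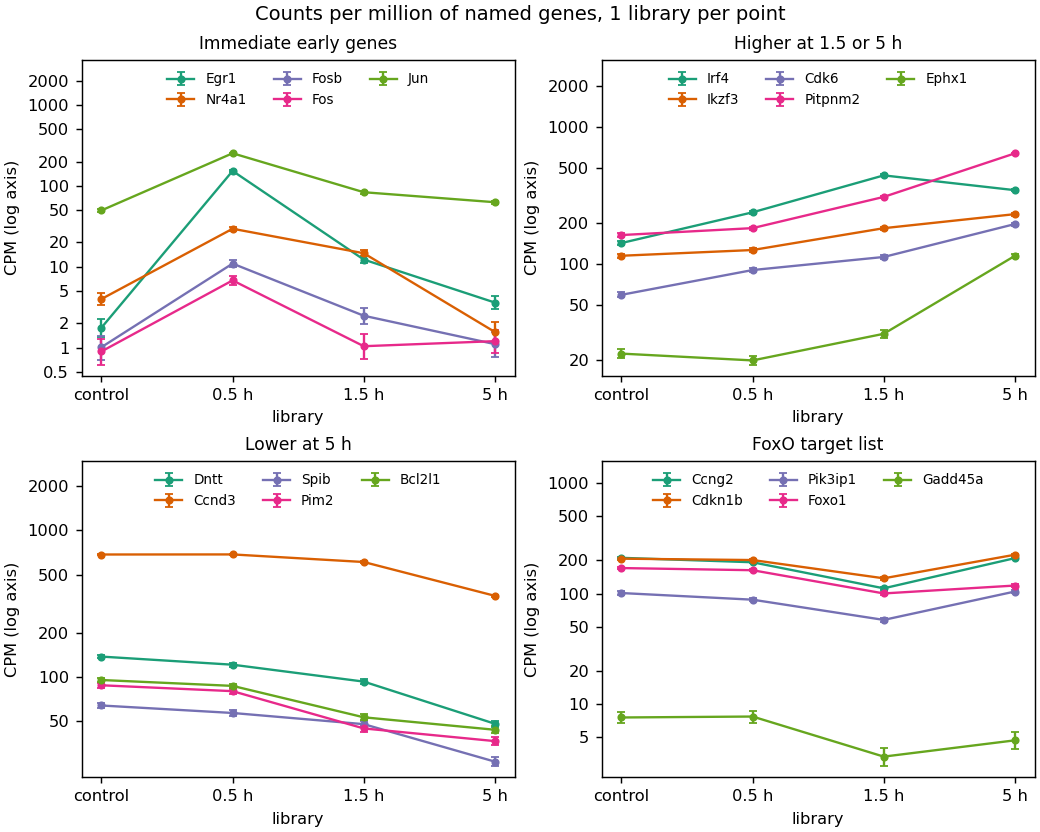
Points show CPM (log axis) of single genes in the control, 0.5, 1.5 and 5 h libraries, and bars show 95% counting intervals, with 1 library per time. Egr1 reaches 153 CPM at 0.5 h and 3.61 CPM at 5 h, Irf4 reaches 445 CPM at 1.5 h, Dntt is at 48.0 CPM at 5 h, and Ccng2 is at 111 CPM at 1.5 h.

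At 5 h, the comparison with control addressed later changes. Ephx1 (chromosome 1, 180976155 to 181020904), a microsomal epoxide hydrolase, was 5.19-fold higher (4.80 to 5.62). Pitpnm2 (chromosome 5, 124118690 to 124249760), a phosphatidylinositol transfer protein, was 3.96-fold higher (3.84 to 4.08) at 645 CPM. Cdk6 (chromosome 5, 3343893 to 3523218), a kinase that partners D-type cyclins, was 3.29-fold higher (3.13 to 3.46), and Twsg1, a modulator of BMP signalling, 3.14-fold higher (3.04 to 3.25). Dntt (chromosome 19, 41029275 to 41059523), the terminal transferase that adds nucleotides at heavy chain joints in pro-B cells, went from 138 to 48.0 CPM, 2.87-fold lower (2.71 to 3.04).

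In the light chain recombination list, 2 genes were called higher and 2 lower of 17 at 5 h. Of the 17, 12 were below 0 and 5 above, with a median of -0.24 (-0.29 to -0.083). Irf4 was 2.44-fold higher (2.35 to 2.52) and Ikzf3 (chromosome 11, 98464902 to 98546031), the transcription factor Aiolos, 2.02-fold higher (1.94 to 2.10). Dntt and Spib (chromosome 7, 44525995 to 44532071), an Ets-family factor at 2.41-fold lower (2.23 to 2.62), were the lower ones. Ikzf3 sat at the limit of the rule, and its call ended with a log2 ratio of 0.999 without lane 2, 0.997 in unique reads, 0.98 with a pseudocount of 5 CPM, and 0.99 in the authors' fold change. Transcription factors of the B lineage went both ways, with 14 of 24 above 0, 10 below and a median of 0.11. Lef1 was 1.75-fold (1.71 to 1.79) and Bach2 1.64-fold higher (1.59 to 1.69), and Erg, an Ets-family factor, 1.76-fold lower (1.71 to 1.82), all outside the rule. The 1 member called was Gfi1b, a transcriptional repressor at 2.64-fold lower (1.99 to 3.55), whose call ended without lane 2 (log2 ratio -0.96) and with a pseudocount of 5 CPM (-0.58). Rag1 was at 4.68 CPM and Rag2, its partner, at 5.98 CPM, each within 1.5-fold of control and with at most 20% of reads uniquely placed. In the pro-B marker list 2 of 12 were called lower, Dntt and Bst1, an ectoenzyme at 2.09-fold lower (1.88 to 2.33), whose log2 ratio of -1.02 became -0.96 without lane 2, -0.93 without lane 4, -0.87 with a pseudocount of 5 CPM and -0.93 in total gene reads.

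IL-7 and STAT5 targets were lower at 5 h, with 3 of 21 called and 16 below 0, and a median of -0.16. Pim2 was 2.40-fold lower (2.24 to 2.57) and Bcl2l1 2.18-fold lower (2.05 to 2.33). The third was Gfi1b, whose call ended without lane 2 (log2 ratio -0.96) and with a pseudocount of 5 CPM (-0.58). Cyclin D3, Ccnd3, a cyclin of pre-B cell proliferation, went from 685 to 358 CPM, 1.91-fold lower (1.87 to 1.96), just outside the rule. The G1 list had a median of -0.20 with Cdk6 alone called. S phase genes had a median of -0.19 with 22 of 25 below 0 and 0 called, including Uhrf1, a factor that maintains DNA methylation, at 1.61-fold lower (1.57 to 1.65). Genes of G2 and mitosis had medians of -0.01, -0.12 and -0.06 at the 3 times, with 0 of 25 called.

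The ribosome biogenesis list was above control at 5 h, with a median of 0.57 (0.49 to 0.60) and 29 of 30 genes above 0, though 0 were called. Gar1 and Nolc1, which act in processing of ribosomal RNA, were 1.88-fold (1.76 to 2.0) and 1.77-fold higher (1.71 to 1.84), while Myc itself was 1.16-fold higher (1.13 to 1.19). All 22 sterol synthesis genes were below 0, with a median of -0.34 (-0.59 to -0.24) and 0 called. Hmgcs1 (chromosome 13, 119690462 to 119708086), which makes HMG-CoA, was 1.76-fold lower (1.71 to 1.82). Heat shock genes had a median of 0.26 (-0.055 to 0.31). FoxO targets had a median of -0.14 with 0 called.

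Of 20 receptor components 15 were below 0 at 5 h and 5 above, with a median of -0.24 (-0.32 to -0.097), below all random lists, and 0 called. Cd79a was 1.48-fold lower (1.46 to 1.50) and Ighm 1.25-fold lower (1.24 to 1.26), while Cbl was 1.33-fold (1.26 to 1.39), the kinase gene Blk 1.17-fold (1.11 to 1.23) and Btk, another kinase gene, 1.15-fold higher (1.12 to 1.18). At 0.5 and 1.5 h this list had medians of -0.07 and -0.08. The immediate early list was at -0.04, and 1 of its 30 genes was called lower. This gene was Klf10, a zinc finger factor at 2.18-fold lower (1.87 to 2.56), whose call ended without lane 1 (log2 ratio -0.94) and with a pseudocount of 5 CPM (-0.77). In the unfolded protein response list, with a median of -0.12, Trib3, a pseudokinase, was called at 2.31-fold lower (2.02 to 2.64), a call that ended with a pseudocount of 5 CPM (-0.90). Interferon response genes, of which 11 of 22 were measured, had medians of -0.12 (-0.23 to 0.0062), -0.26 (-0.67 to 0.051) and -0.36 (-0.59 to -0.14) at the 3 times. Among them Gbp2, a guanylate-binding protein, was 2.54-fold lower at 5 h (1.90 to 3.45), a call that ended without lane 3 (-0.98), in total gene reads (-0.96) and with a pseudocount of 5 CPM (-0.53).

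In total 32 genes were called higher and 38 lower at 5 h, of 9520. Further genes with large ratios lay outside the called members of these lists. Nlrp3 (chromosome 11, 59541568 to 59566956), an inflammasome sensor, was 12.1-fold lower (7.87 to 19.7), Tgfb3 (chromosome 12, 86056744 to 86079041), a TGF-beta ligand, 7.72-fold lower (6.15 to 9.81), and Bank1, a B cell scaffold protein, 3.76-fold lower (3.11 to 4.59). Lta, the cytokine lymphotoxin alpha, was 2.93-fold lower (2.68 to 3.20). Pdcd1 (chromosome 1, 94038307 to 94052553), which encodes the receptor PD-1, went from 0.376 to 5.40 CPM, 14.3-fold higher (8.16 to 27.5). Its call ended in total gene reads, where its log2 ratio was 2.08 but its level of 4.55 CPM was under the floor, and with a pseudocount of 5 CPM, at a log2 ratio of 0.95. Tsix, the antisense RNA of Xist, was called at 3.18-fold higher (2.68 to 3.78), but 5% of its reads were uniquely placed, its unique reads numbered 12 in the control library and 22 at 5 h (2.05-fold, 0.970 to 4.54), under the floor, its log2 ratio of 1.50 was 0.998 in total gene reads, which ends the call, and the strand of counting is not stated.

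The libraries at 5 and 1.5 h were compared directly to separate early from late changes. Of 9453 genes, 9 were higher at 5 h and 42 lower. Genes of the first response were lower at 5 h. Nr4a1 was 9.42-fold lower (6.99 to 13), Egr1 3.40-fold (2.75 to 4.24) and Myc 2.57-fold lower (2.51 to 2.63), and the immediate early list had a median of -0.59 with 6 of 31 called lower. Klf16, a zinc finger factor, was 3.59-fold lower (3.22 to 4.02) and Plekho2, a pleckstrin domain protein, 3.29-fold lower (3.08 to 3.52). NF-kB and NFAT targets had a median of -0.35, with 2 called lower, Nfkbid at 2.30-fold (2.05 to 2.58) and Tnf at 2.64-fold (2.13 to 3.29). Both calls ended with a pseudocount of 5 CPM, at log2 ratios of -0.97 and -0.77.

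Sterol synthesis genes were lower at 5 h than at 1.5 h in all 22 measured members, with a median of -0.61, below all random lists. Hmgcs1 was called at 2.33-fold lower (2.26 to 2.40). The unfolded protein response list had a median of -0.31 with 0 called. FoxO targets went both ways, with 15 of 24 above 0, 9 below and 0 called. Their median of 0.23 was above all random lists, but its interval includes 0 (-0.057 to 0.39). In this list Ccng2 was 1.88-fold higher (1.8 to 1.96), Pik3ip1, an inhibitor of PI3 kinase, 1.81-fold higher (1.71 to 1.92) and Cdkn1b 1.64-fold higher (1.58 to 1.70). Ephx1 was 3.72-fold higher (3.47 to 3.99), and Trp53inp1, a p53 target, 2.07-fold higher (2.01 to 2.13). At 1.5 h Trp53inp1 had been 1.77-fold lower than in control (1.72 to 1.83). Pitpnm2 was 2.08-fold higher (2.03 to 2.13), a call that ended in total gene reads at a log2 ratio of 0.86.

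**Figure D3:**
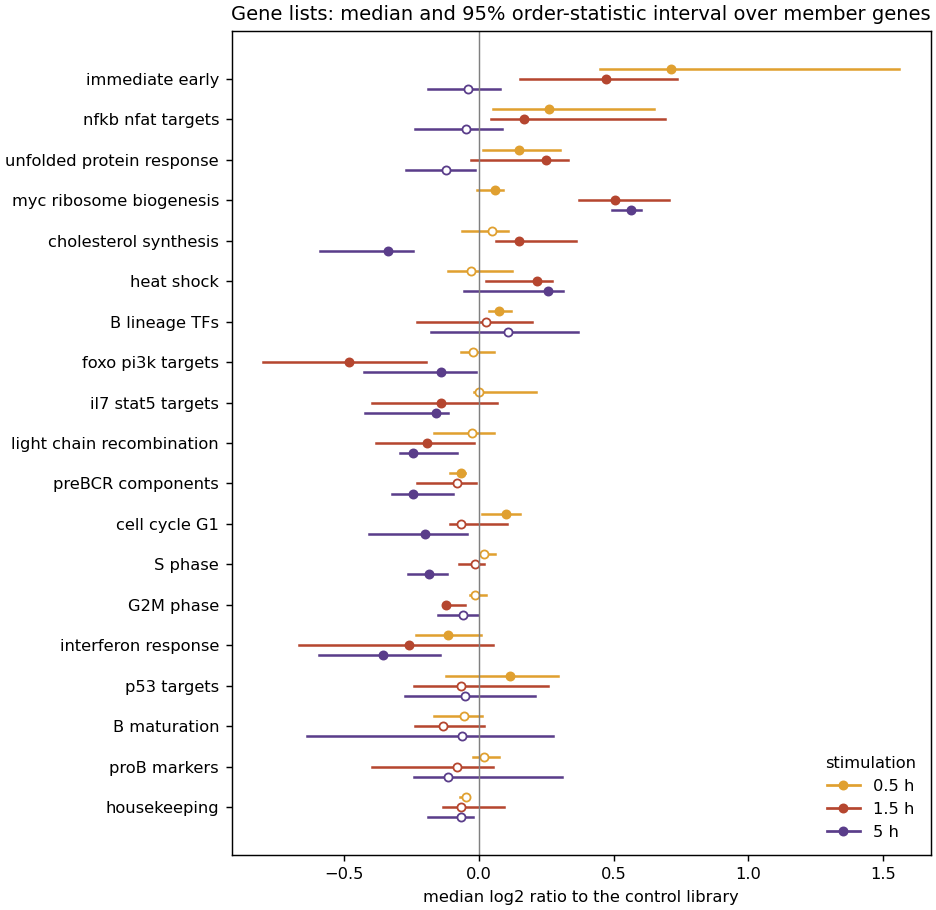
Points show the median log2 ratio of each gene list in the 0.5, 1.5 and 5 h libraries against control, with 95% order-statistic intervals over member genes; filled points lie in the outer 5% of 10000 random lists. The immediate early list goes from 0.71 at 0.5 h to -0.04 at 5 h, ribosome biogenesis reaches 0.57 at 5 h, and FoxO targets are at -0.48 at 1.5 h.

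Over the time course, 99 genes were called higher and 57 lower at any time, and 0 were called in both directions. The largest ratio of the higher genes fell at 0.5 h for 23, at 1.5 h for 48 and at 5 h for 28. For the lower genes these numbers were 2, 19 and 36. Irf4 was called at 1.5 and 5 h, with a ratio of 1.68-fold at 0.5 h (1.62 to 1.74). Hist1h2ap, a histone gene with 28% of reads uniquely placed, was the 1 gene called higher at all 3 times, at 4.06-fold at 1.5 h (3.25 to 5.10). In unique reads it was 6.77-fold higher at 1.5 h (3.98 to 12.3), but at 3.73 CPM, under the floor, and 9.35-fold at 5 h (5.55 to 16.8), at 5.15 CPM.

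The 3 comparisons share 1 control library, so their ratios are not independent. Across 9405 genes, which are not independent replicates, the log2 ratios of 0.5 and 1.5 h correlated at 0.50, those of 0.5 and 5 h at 0.29 and those of 1.5 and 5 h at 0.62. Simulated unchanged genes gave 0.49, 0.48 and 0.48. The covariances were 0.0252, 0.0148 and 0.0527, against 0.0018 in the simulation, and with the control lanes split between the comparisons they were 0.0227, 0.0123 and 0.0502. Splitting lanes removes sequencing noise but not differences of the control library itself, so part of the excess may come from the shared control. Between 0.5 and 1.5 h, 12 genes were called higher in both, against 0.136 for independent calls. Between 1.5 and 5 h, 8 were higher and 3 lower in both (0.167 and 0.0802 for independent calls), and between 0.5 and 5 h 2 were higher in both (0.0521). The 3 lower genes were B3gnt8, Pgf and Nlrp3, whose 1.5 h call ended with a pseudocount of 5 CPM (log2 ratio -0.69), and the 2 higher ones were Hist1h2ap and Tsix, with 28 and 5% of reads uniquely placed. The simulation gave 0 for each overlap. With counting error alone, unchanged genes at this depth do not reach the rule of size. That 0 was therefore fixed in advance and says nothing on differences between libraries.

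Most markers of other cell types were below 1 CPM. Of the 16 T and NK cell markers 3 were measured, Cd28, Lck and Klrb1c, at 19.8, 36.1 and 16.3 CPM in the control library, with list medians of -0.01, -0.01 and 0.22 at the 3 times. Cd3e, a chain of the T cell receptor complex that was chosen after its values were seen, had 0 reads in the control library, where a count of 0 allows up to 0.0869 CPM. Of the 19 myeloid markers 6 were measured, with medians of 0.00, -0.09 and -0.29. Among these at 5 h the integrin gene Itgam was 1.92-fold lower (1.79 to 2.06) and Cybb, an oxidase subunit, 1.78-fold higher (1.70 to 1.86). Itgax, another integrin, was called at 2.51-fold lower (1.89 to 3.38), but its call ended without lane 2 (log2 ratio -0.99) and lane 3 (-0.89), in unique reads (-0.97) and with a pseudocount of 5 CPM (-0.54). Erythroid and megakaryocyte markers had 2 of 15 measured, with medians of -0.06, -0.01 and -0.08, and the stromal list had 1, 2 and 2 of 15, with medians of 0.25, 0.38 and 0.09. B cell maturation genes had medians of -0.06, -0.13 and -0.06, pro-B markers 0.02, -0.08 and -0.11, plasma cell genes 0.14, -0.02 and -0.03, p53 targets 0.12, -0.07 and -0.05, and housekeeping genes -0.05, -0.07 and -0.07. In the p53 list Aen, a nuclease, was called higher at 1.5 h at 2.44-fold (2.27 to 2.64).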

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

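Of the tests in this part, those on reads shared between genes and on reads outside exons were chosen only after the result was seen, as was the size that a list median had to pass to be given here.

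The first pattern is the immediate early response at 0.5 h, with a median log2 ratio of 0.71 over 32 genes. Counting unique reads alone gave 0.71 (0.45 to 1.56), which argues against reads shared between genes as its cause. Taking out running medians over GC content and exon length left 0.71 (0.47 to 1.54), which argues against a trend of that kind. The biological explanation is signalling through the induced fusion. A response to the inducing drug or to handling may give the same genes and cannot be told apart from it, since 0 libraries came from cells given the drug without the fusion, and it is not stated whether the control cells received the vehicle of the drug.

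The second pattern is the sterol synthesis list, which was above control at 1.5 h and below control at 5 h, a difference of -0.48 between the list medians that was not tested. Directly between the libraries at 1.5 and 5 h the median was -0.61 over 22 genes. Unique reads gave -0.58 (-0.74 to -0.43), and taking out GC content and length left -0.60 (-0.77 to -0.43), so neither shared reads nor such a trend accounts for it. Passing induction of sterol synthesis by the receptor signal is a candidate explanation that was not tested. An effect of the inducing drug, which stays open for want of cells given the drug without the fusion (0 libraries), cannot be told apart from it.

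The third pattern is in reads outside exons, which the comparisons of the report do not use. They made up 13.8% of unique gene reads at 1.5 h and 14.6% at 5 h, above the 13% of the control library. With 1 library per condition and its kit not stated, differences of library preparation cannot be told apart from time here. Of 32 genes called higher at 5 h, 26 had enough reads, and 20 of these had a higher ratio outside exons than in exons at 1.5 h. The median difference was 0.29 (0.23 to 0.35), at percentile 99.93 of random gene sets. In exons these genes already had a median log2 ratio of 0.68 at 1.5 h, against 1.18 outside exons. The random sets were matched on expression and not on change, so the percentile does not show that reads outside exons rose first. New transcription ahead of spliced RNA may account for the difference. For genes called higher at 1.5 h the difference at 0.5 h was 0.26 (0.20 to 0.39), at percentile 100, but 41 of 61 had enough reads, too few for this check, so that explanation stays open for them. Over the other genes the same difference was 0.0726 at 1.5 h and -0.00098 at 0.5 h, both below these intervals, which argues against a general rise of reads outside exons as the whole cause, though at 1.5 h there was such a rise.

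The G1 phase list was above control at 0.5 h and below it at 5 h, a difference of -0.30 that was not tested. No lane stood apart from the others of its library in 12 groups of lane values, where chance gives about 1 in 20.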

How the results depend on the processing

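The tests with unique exon reads, total gene reads and the authors' fold change were chosen only after the result was seen. Depth limits the naming of genes near 5 CPM, and calls rest on size alone. Numbers are given as higher and then lower. At 1.5-fold the calls were 64 and 14 at 0.5 h, 321 and 189 at 1.5 h, 210 and 284 at 5 h, and 123 and 200 from 1.5 to 5 h. At 4-fold they were 8 and 0, 2 and 0, 2 and 2, and 0 and 1 in the same order, and 10 and 2 over the time course, by construction of a stricter limit. With a floor of 20 CPM there were 16 and 1 at 0.5 h, and 10, 21 and 27 lower genes at 1.5 h, 5 h and from 1.5 to 5 h, since fewer genes qualify. A pseudocount of 0.1 CPM gave 4 lower genes at 0.5 h and 14 higher from 1.5 to 5 h. A pseudocount of 5 CPM gave 19 and 0 at 0.5 h, 32 and 6 at 1.5 h, 20 and 16 at 5 h, and 6 and 26 from 1.5 to 5 h, as it shrinks ratios of weak genes. The order of the reported 32 and 38 at 5 h thus reversed. It also reversed with a floor of 20 CPM (24 and 21) and in total gene reads (35 and 33). At 4-fold the numbers at 5 h were equal, and under the other alternatives lower genes stayed more numerous. The 2 lower genes at 0.5 h became 0 in unique reads, where Ramp2 and Gm8399 had at most 1 read in either library. The count was 4 in total gene reads and 5 in the authors' fold change. That fold change also gave 32 lower genes at 1.5 h, and it was not run from 1.5 to 5 h, since it is against control. The cause of the changed counts in total gene reads and in the authors' fold change was not tested. Leaving out each lane in turn gave 27 to 29 higher and 1 (without lane 1, sharing 0 with the 2 reported) to 4 (without lane 3) lower genes at 0.5 h, 59 to 65 and 19 to 26 at 1.5 h, 32 to 38 and 35 to 42 at 5 h, and 9 to 13 and 44 to 48 from 1.5 to 5 h.

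The list mean in place of the median moved the receptor components at 0.5 h to -0.046 and the B lineage factors at 0.5 h to 0.15. It reversed the ribosome biogenesis list from 1.5 to 5 h, from a median of 0.09, whose interval includes 0 (-0.21 to 0.20), to a mean of -0.025. The cause was not tested. Ramp2 at 0.5 h came to 0.050 in unique reads, but with 0 such reads in the control library and 1 at 0.5 h this value holds no direction. Of the 144 counts of genes under alternatives, 107 stayed within 1.5 times the reported count and 37 did not. Of 480 values of lists with an interval 474 stayed within it, and of 116 values of lists with fewer than 6 measured genes 102 stayed within the range of the members. Of 5640 values of named genes 5383 moved by no more than the half-width of their counting interval. This tally pools unlike alternatives. A pseudocount of 5 CPM moved 77 of 480 values and total gene reads moved 76 of 480. Leaving out a lane moved at most 4 of 480, but lanes of 1 library cannot show differences between libraries. The largest move of the median log2 ratio under TMM or DESeq2 factors was at 1.5 h with TMM, from -0.0050 to 0.016. Having no floor is the same as a floor of 1 CPM under the rule of size. The largest row per gene and the authors' adjusted p-values were not run as alternatives, since 0 feature names are duplicated and no p-value was used. The entry of Gbp11 is named with its coordinates, so a gene may have more than 1 entry under different names. This was not tested.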

Other observations

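The tests on circadian clock genes and on reads outside exons in this part were chosen only after the result was seen, as were the genes shown.

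Of 12 measured genes in a list of 20 circadian clock genes, 2 were called higher and 1 lower at 1.5 h, and 9 were not called. Nr1d1, a repressor in the clock's feedback loop, went from 8.98 to 30.6 CPM, 3.41-fold higher (3.0 to 3.88), and the period gene Per1 from 50.0 to 122 CPM, 2.43-fold higher (2.30 to 2.58). Arntl, which encodes the clock activator BMAL1, was 2.21-fold lower (1.98 to 2.48). The log2 ratios of the 9 others ran from -0.043 (Tef) to 0.73 (Per2, 1.69-fold higher, 1.53 to 1.87). At 5 h 0 of the 12 were called, though Nr1d2 was 2.09-fold higher (1.81 to 2.41) at a log2 ratio of 0.98. The list was written after these values were seen and holds the called genes, so its percentiles among random lists (99.88 at 1.5 h and 85.3 at 5 h) do not decide whether clock genes moved as a group, which stays open.

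Unique reads outside exons were also counted for single genes, as numbers of reads not scaled for depth. For Irf4 they numbered 365 in the control library, 1604 at 0.5 h, 1630 at 1.5 h and 960 at 5 h, and its exon level was also highest at 1.5 h. For Myc they were 554, 2324, 1374 and 583 in the same order. For Pitpnm2 they were 1273, 1760, 4695 and 5865, and for Ikzf3 1736, 2295, 3858 and 4288, with the highest value at 5 h in both. For Dntt they were 1404, 976, 494 and 737, lowest at 1.5 h, whereas its exon level was lowest at 5 h. For Ccnd3 they were 2919, 3052, 2223 and 2801, while its exon level was lowest at 5 h.

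The 78 ribosomal protein genes had median log2 ratios of -0.03, -0.08 and -0.06 at 0.5, 1.5 and 5 h in total exon reads, and 0.01, 0.02 and 0.01 in unique reads, which are 36.2% of their reads.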
